A study of Homo sapiens with 4 samples.

How the data were processed

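Ribosome-associated mRNA was measured in primary human umbilical vein endothelial cells, cultured cells from the lining of the umbilical cord vein. Per the labels' protocols and the series' design text, cells received lipopolysaccharide (LPS, a bacterial endotoxin) at 1 µg/mL, or a buffered salt solution as vehicle, for 2 h. Translation was then frozen with cycloheximide at 100 ng/mL for 5 min, and lysates were spun through gradients of 15 to 50% sucrose at 43700 rpm for 90 min. RNA from the monosome pool (mRNA on a single ribosome) and from the polysome pool (mRNA on several ribosomes) was copied from its poly(A) tail into radioactive cDNA, which was hybridised to 4 identical nylon filters carrying human cDNA clones and read with a phosphorimager and the Pathways software.

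Groups were taken from the sample titles, which give 4 groups with 1 filter each: control monosome, control polysome, LPS monosome and LPS polysome. The labels disagree here. The source text of both samples titled LPS names the vehicle, and the description of every sample calls it the control monosome fraction and speaks of histamine. The titles alone separate the 4 samples in a way that fits the series title, and all directions given below rest on them.

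The deposited values are spot intensities on a linear scale, 4132 spots per filter. Per the design text, the authors divided each spot's raw intensity by the average intensity of its filter and kept spots whose signal was over 1.1 times the background between spots. In the deposited values the median is exactly 1 on every filter and the arithmetic means lie between 3.46 and 3.85, so that the divisor was the median, or an average other than the arithmetic mean. Background values were not analysed here, and the screen on background was therefore not repeated. No background subtraction is mentioned in the sources used here.

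Each filter was divided by its arithmetic mean over all spots, which is how the word average in the design text was read here before the values were seen. The deposited medians of 1 do not bear this reading out, and scaling to the median was an alternative. Ratios were taken on the log2 scale. The translation state is polysome over monosome signal within a treatment. As each filter is scaled to itself, it ranks mRNAs against each other and does not give the share of an mRNA on polysomes. The translation index is the LPS translation state divided by the control translation state, and its upper and lower limits, 2.5 and 0.4, are those of the design text. LPS over control was taken in each fraction with the same limits, and spots at least 2-fold higher, or at 0.5 or lower, in both fractions were counted beside the number that independent lists would share. Spots entered when their mean log2 signal over the 4 filters was at or above its 25th percentile, which kept 3099 spots and left out 1033.

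Spots were named through a table of the platform's annotation, with symbols updated by gene ID through the table of human genes of assembly GRCh38.p14, which was used for names only. Of the 4132 spots, 1582 were paired with 1 gene symbol, 52 with several and 2498 are unnamed here. Of the 1582, 1580 were matched by gene ID and 2 symbols were updated by it. No gene was named from a spot with several symbols. The 3099 spots included 1200 spots with 1 gene symbol. Without the spots of Y-linked genes and the X-inactivation transcript, these gave 1169 named genes, and the log2 values of the 25 genes with more than 1 spot were averaged.

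With 1 filter per group there is no replicate, no test between treatments and no standard deviation of any signal. Nothing in the sources used here says how many cultures went into a filter. The only error available is the spread between different spots of 1 gene, pooled over 54 spots of 25 genes, and the intraclass correlation of those spots, with a one-sided permutation test of 100000 draws and Benjamini-Hochberg adjustment over the 5 ratios. In 21 of the 25 genes the spots share a clone accession, on consecutive spots in 19, so the spread and the correlation rest largely on neighbouring spots listed for the same clone. They leave out all differences between cultures, gradients and hybridisations.

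Lists for 19 gene groups were fixed before the data were examined, together with the ratios, limits, main filter and alternatives, except for 1 filter on dim spots, which is named as a later choice where it is used. They cover NF-kB inflammatory genes, immediate early genes, interferon response genes, TLR4 and NF-kB signalling components, cytosolic ribosomal proteins, translation factors, mitochondrial oxidative phosphorylation, proteasome subunits, chaperones, endothelial markers, extracellular matrix, cytoskeleton, cell cycle, apoptosis regulators, splicing and RNA-binding proteins, and markers of leukocytes, erythroid cells, smooth muscle or fibroblasts, and epithelium. The median of each list with at least 3 measured genes was placed among the medians of 10000 random lists of the same size, matched on mean signal in 10 bins. This percentile describes these 4 filters and is no test of the treatment. Of 85 list and ratio pairs, 14 lay outside the central 95% of random lists, where 4.25 would by chance.

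Genes were named by size among genes whose signal was at or above the 25th percentile of each filter in the ratio. The rule took the 12 highest and 12 lowest translation indices, the 8 highest and 8 lowest control translation states, and the 10 highest and 10 lowest genes by the smaller of the LPS ratios in the 2 fractions among genes with the same direction in both. It added up to 4 members of each list with the largest values and 24 genes of textbook importance whatever their value. Of these 24, 6 were named on spots here. Y-linked genes and the X-inactivation transcript were not named.

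The alternatives were scaling to the filter median or 75th percentile, the values as deposited, quantile normalization, a loess trend with a span of 0.4 removed from each ratio, subtraction of each filter's 1st percentile as background, a pseudocount of 0.1 filter means, other filters on dim spots, a floor at the 25th percentile, genes in place of spots, other limits, unmatched random lists and means in place of medians. Calculations were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. The steps were tested on simulated data of 4132 spots, where a planted 4-fold translation index passed the limits in 98% of the spots planted higher and 96% of those planted lower, and 0.0345% of 2899 spots with no planted difference passed. Differences were planted only in spots neither dim nor among the brightest. Noise was independent and of equal size on every filter, without background or a trend with signal. These rates check the steps and do not give the error rate of the real calls. For lists drawn over 1163 genes, 5.5% of 200 lists with no shift and 93% of 100 lists shifted 1.41-fold fell outside the central 95%.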

Results

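Signals of monosome-bound and polysome-bound mRNA were read on 4 filters of 4132 cDNA spots, 1 filter each for vehicle-treated and LPS-treated endothelial cells in each fraction. Mean deposited intensity relative to the filter median was 3.72 on the control monosome filter, 3.46 on the control polysome filter, 3.85 on the LPS monosome filter and 3.57 on the LPS polysome filter. The brightest 41 spots held 41.8% and 41.1% of all signal on the monosome filters and 34.6% and 34.4% on the polysome filters, control first. Log2 signals of different filters correlated across spots with Pearson's r between 0.925 and 0.966. There was 1 filter per group, so no value below has a replicate error and no difference between treatments was tested. Fold values are ratios of signals divided by the filter mean.

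The first comparison asked which mRNAs differed in amount on ribosomes after 2 h of LPS, in each fraction. CX3CL1, the membrane-bound chemokine fractalkine, was 15.9-fold higher on the LPS polysome filter and 14.04-fold higher on the LPS monosome filter than on the matching control filter. SOD2, the mitochondrial superoxide dismutase and a known NF-kB target, was 10.1-fold and 4.63-fold higher. RCAN1, a regulator of the phosphatase calcineurin, was 8.53-fold higher on the polysome and 2.69-fold higher on the monosome filter, and CFLAR, an inhibitor of caspase-8 activation, 5.41-fold and 2.75-fold. ESM1, a proteoglycan secreted by endothelial cells, was 3.90-fold and 3.72-fold higher. By comparison, 2 SDs between different spots of 1 gene came to 1.44-fold for the polysome ratio and 1.45-fold for the monosome ratio.

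Further down this ranking, NNMT, which methylates nicotinamide, was 2.51-fold higher on the polysome and 2.14-fold higher on the monosome filter. The endocytic ATPase EHD1 was 2.25-fold and 1.95-fold higher, the early response gene IER3 2.06-fold and 1.90-fold, the interferon-induced exonuclease ISG20 3.37-fold and 1.81-fold, and the actin-nucleating subunit ARPC2 2.99-fold and 1.77-fold. In the other direction, EXT2, an enzyme of heparan sulfate synthesis, stood at 0.435 of control on the polysome and 0.425 on the monosome filter. DPF2 stood at 0.442 and 0.279, SPRY1, an antagonist of growth factor signalling, at 0.456 and 0.397, and the receptor kinase GRK2 at 0.458 and 0.457. HAAO, IL13RA2, RGN, SORL1, TRIO and CAPRIN1 completed the 10 lowest, with polysome ratios between 0.321 for RGN and 0.660 for CAPRIN1. LPS polysome signals of EXT2, DPF2, SPRY1 and GRK2 were 0.193, 0.207, 0.207 and 0.248 of the filter mean. This is close to the dim end, where background weighs on the size of a ratio, while HAAO and CAPRIN1 were brighter, at 0.498 and 0.478.

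**Figure D1:**
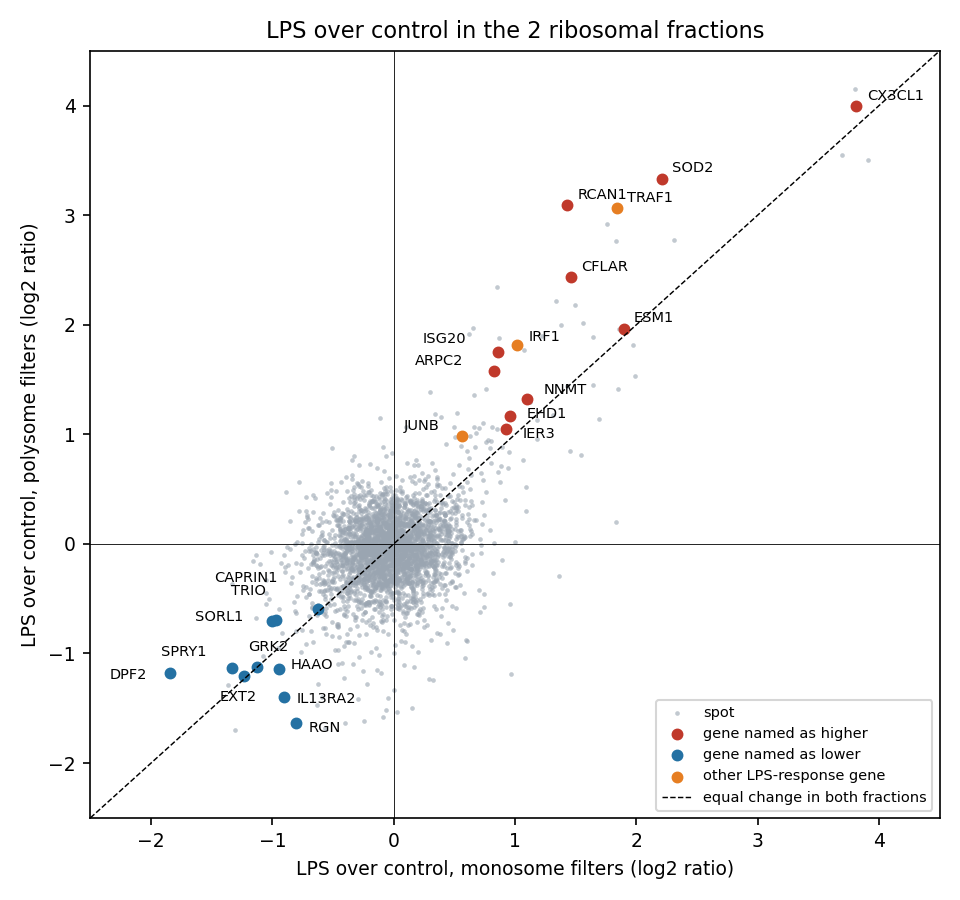
LPS over control in the monosome fraction (horizontal axis, log2 ratio) against the polysome fraction (vertical axis, log2 ratio) for spots in grey, with the 10 highest and 10 lowest named genes in red and blue, 3 other LPS-response genes in orange and a dashed line of equal ratios. Grey spots are the 3099 without those of Y-linked genes and the X-inactivation transcript. CX3CL1 lies near the dashed line at 15.9-fold and 14.04-fold, while SOD2, RCAN1 and TRAF1 lie above it.

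Of 3099 spots, 36 were at least 2.5-fold higher on the LPS polysome filter and 15 were at 0.4 or lower. On the monosome filters 28 were higher and 4 lower by the same limits. With the 1st percentile subtracted the splits were 43 against 32 and 37 against 18, and with the pseudocount 29 against 5 and 18 against 1. With scaling to the filter median they were 37 against 14 and 29 against 1. At least 2-fold higher in both fractions were 31 spots, where independent lists of 54 polysome and 39 monosome spots would share 0.680. The 10 of these with a gene name were CX3CL1, SOD2, TRAF1, RCAN1, CFLAR, ESM1, IRF1, IL18R1, NNMT and SEMA5A. At 0.5 or lower in both were 7 spots, against 0.227 for independent lists of 39 and 18. The polysome and monosome ratios share no filter, and across the 3099 spots, which are not independent replicates, they correlated with Pearson's r of 0.503 and Spearman's rho of 0.227. Both fractions of a treatment may come from the same cultures. A difference between cultures unrelated to LPS could then appear in both ratios, so their agreement is no second measurement of LPS.

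NF-kB inflammatory genes were higher together on the LPS filters. The 9 members measured, of 51 listed, had a median of 2.62-fold on the polysome and 2.02-fold on the monosome filters, both at percentile 100 of the random lists. Over 13 alternatives this log2 median ran from 0.95 to 3.06 on the polysome and from 0.80 to 1.84 on the monosome filters, lowest with the pseudocount and highest over the 5 members with mean signal above its median. At least 1.5-fold higher were 7 of 9 in each fraction. TRAF1, an adaptor of the TNF receptor family, was 8.36-fold and 3.57-fold higher, and the transcription factor IRF1 3.52-fold and 2.02-fold. CD83 was 2.62-fold and 1.23-fold higher, IL18R1, an interleukin-18 receptor chain, 2.19-fold and 2.27-fold, and GCH1, the first enzyme of tetrahydrobiopterin synthesis, 1.48-fold and 1.52-fold. IL15 stood at 1.36 and 0.998. Control signals of CX3CL1, TRAF1, IRF1, CD83, IL18R1, GCH1 and IL15 were under 0.25 of the filter mean, close to the dim end of the filters, where background left in the signal weighs most.

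**Figure D2:**
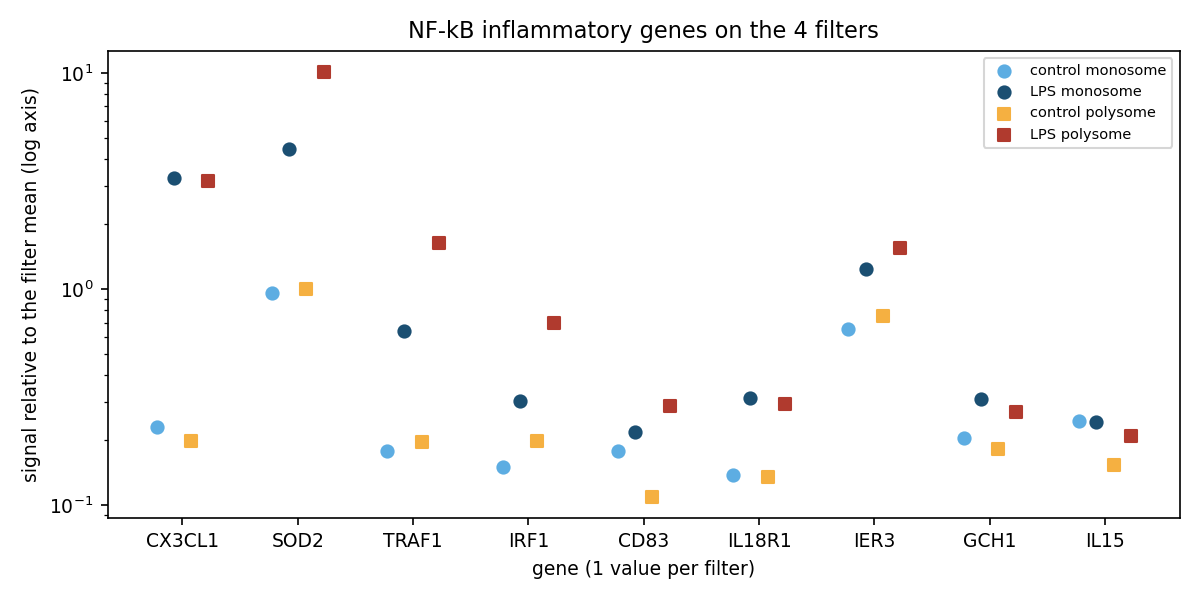
Signal relative to the filter mean (vertical log axis) of the 9 measured NF-kB inflammatory genes on the 4 filters, with circles for monosome and squares for polysome filters, light for control and dark for LPS, 1 value per filter and no error bar. SOD2 and IER3 have the brightest control signals, and CX3CL1 goes from 0.231 to 3.25 on the monosome filters.

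Immediate early genes, the fast transcriptional responders to many stimuli, had a median of 1.14-fold on the monosome filters (14 genes, percentile 98.6) and 1.11-fold on the polysome filters (percentile 94.99, inside the central 95%). JUNB was 1.97-fold higher on the LPS polysome and 1.48-fold higher on the monosome filter, DUSP5, a phosphatase of ERK, stood at 1.78 and 0.989, and DUSP6 and KLF4 were 1.67-fold and 1.64-fold higher on the polysome filter. JUN stood at 1.12 and 1.06. Without 1 gene at a time the lowest monosome percentile of this list was 89.3, and with the mean in place of the median it was 92.9. Among 13 apoptosis regulators the polysome median was 1.16-fold (percentile 99.2), with CFLAR as the sole member at 1.5-fold or more and the next, TNFSF10, the death ligand TRAIL, at 1.49. Their monosome median was 1.12-fold (percentile 97.4, inside), and outside the central 95% under 10 of 13 alternatives. The polysome percentile was 95.1 over spots with mean signal above the median. The 10 interferon response genes had medians of 1.09-fold on the polysome (percentile 92.8) and 1.04-fold on the monosome filters, with ISG20 highest and CXCL10 at 1.11 and 0.786.

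Endothelial markers had medians of 0.900 on the polysome and 0.991 on the monosome filters (8 genes, both inside the central 95%), with the junction protein CDH5 at 0.902 and 1.20. The signalling components of TLR4, the LPS receptor, and NF-kB had medians of 0.939 and 1.14 (8 genes, inside), with the adaptor MYD88 at 1.16 and 1.22. Markers of other cell types were inside the central 95% for LPS over control in both fractions. Leukocyte markers had medians of 1.06 on the polysome and 0.945 on the monosome filters (6 genes), smooth muscle and fibroblast markers 0.971 and 1.03 (5 genes), and erythroid markers 0.976 and 0.951 (3 genes). CLDN4, the only epithelial marker measured, stood at 1.17 and 0.972. Mean log2 ratios on the monosome filters had the sign opposite to the median for endothelial (0.07), erythroid (0.02) and smooth muscle and fibroblast markers (-0.03).

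The second comparison asked which mRNAs were rich in polysomes, and which in monosomes, relative to other mRNAs in vehicle-treated cells. The splicing factor SRSF3 had the highest control translation state of the named genes, at 3.65, followed by the respiratory electron carrier CYCS at 3.35, the actin-nucleating subunit ARPC3 at 3.21, MOBP at 3.16, the mitochondrial outer membrane channel VDAC3 at 3.12, NNMT at 3.06, CYB561D2 at 2.98 and the signal recognition particle protein SRP9 at 2.93. The lowest were SMARCD2, a subunit of the SWI/SNF chromatin remodelling complex, at 0.252, DPF2 at 0.374, the actin-binding protein SYNPO at 0.396 and PPP1R10 at 0.399. AFDN, EXT2, PIGC and NPC1 followed between 0.470 and 0.537. MOBP was dim on the control monosome filter, at 0.216 of the filter mean, and whether its signal comes from the named mRNA was not tested. The median over the 3099 spots was 1.10, and 2 SDs between spots of 1 gene came to 1.66-fold.

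Messages for splicing and RNA-binding proteins were polysome-rich as a group relative to random lists, with a median control translation state of 1.74 (14 genes, percentile 100) and 8 of 14 at 1.5 or more. HNRNPD had 2.59, the spliceosomal protein SNRPD2 2.51 and SRSF4 2.22. Proteasome subunits and activators had a median of 1.86 (6 genes, percentile 99.7) with PSME3 at 2.81, PSME1 at 2.59 and PSMD3 at 2.01. The 4 oxidative phosphorylation genes had a median of 2.13 (percentile 99.7), with SDHC at 2.17, NDUFA5 at 2.09 and SDHD at 1.17 beside CYCS. Immediate early genes had a median of 1.40 (percentile 98.4), with a lowest percentile of 96.6, inside the central 95%, when 1 gene at a time was left out. Leukocyte markers had a median of 0.819 (percentile 1.16), and without 1 gene at a time the percentile went up to 5.77. On the control monosome and polysome filters CORO1A had signals of 0.202 and 0.172 and CD79B 0.172 and 0.208, while AIF1 had 1.09 and 0.669. Whether the signals of these markers of another cell type come from the named mRNAs was not tested. Beta-actin, ACTB, measured by 2 spots, had a translation state of 2.36, and RPL31, the only cytosolic ribosomal protein measured, 0.597. Of the brightest 41 spots, only 2 had a control translation state above 1. RPL31 and SMARCD2 were bright, at 22.6 and 20.5 filter means on the control monosome filter, as was ACTB at 12.4. Whether the low states of RPL31 and SMARCD2 go beyond this lean of the brightest spots was not tested.

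In LPS-treated cells the median translation state was 1.67 for splicing and RNA-binding proteins (percentile 100), 2.10 for proteasome genes (percentile 99.97) and 2.11 for oxidative phosphorylation genes (percentile 99.8). Immediate early genes, at 1.34 (percentile 96.1), and leukocyte markers, at 1.08 (percentile 50.4), lay inside the central 95% there, the former outside it under 5 of 13 alternatives. TLR4 and NF-kB signalling components, at 0.854 (percentile 2.59), lay just inside, and outside under 4 of 13 alternatives. ACTB had 2.92, CYCS 3.30, ARPC3 3.30, SMARCD2 0.236, SYNPO 0.460 and EXT2 0.496. Of the 8 genes highest in control, MOBP had 1.22 and CYB561D2 1.69 in LPS-treated cells, and the other 6 had 2.14 or more. Across the 3099 spots, the control and LPS translation states, which share no filter, correlated with Pearson's r of 0.698 and Spearman's rho of 0.612.

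**Figure D3:**
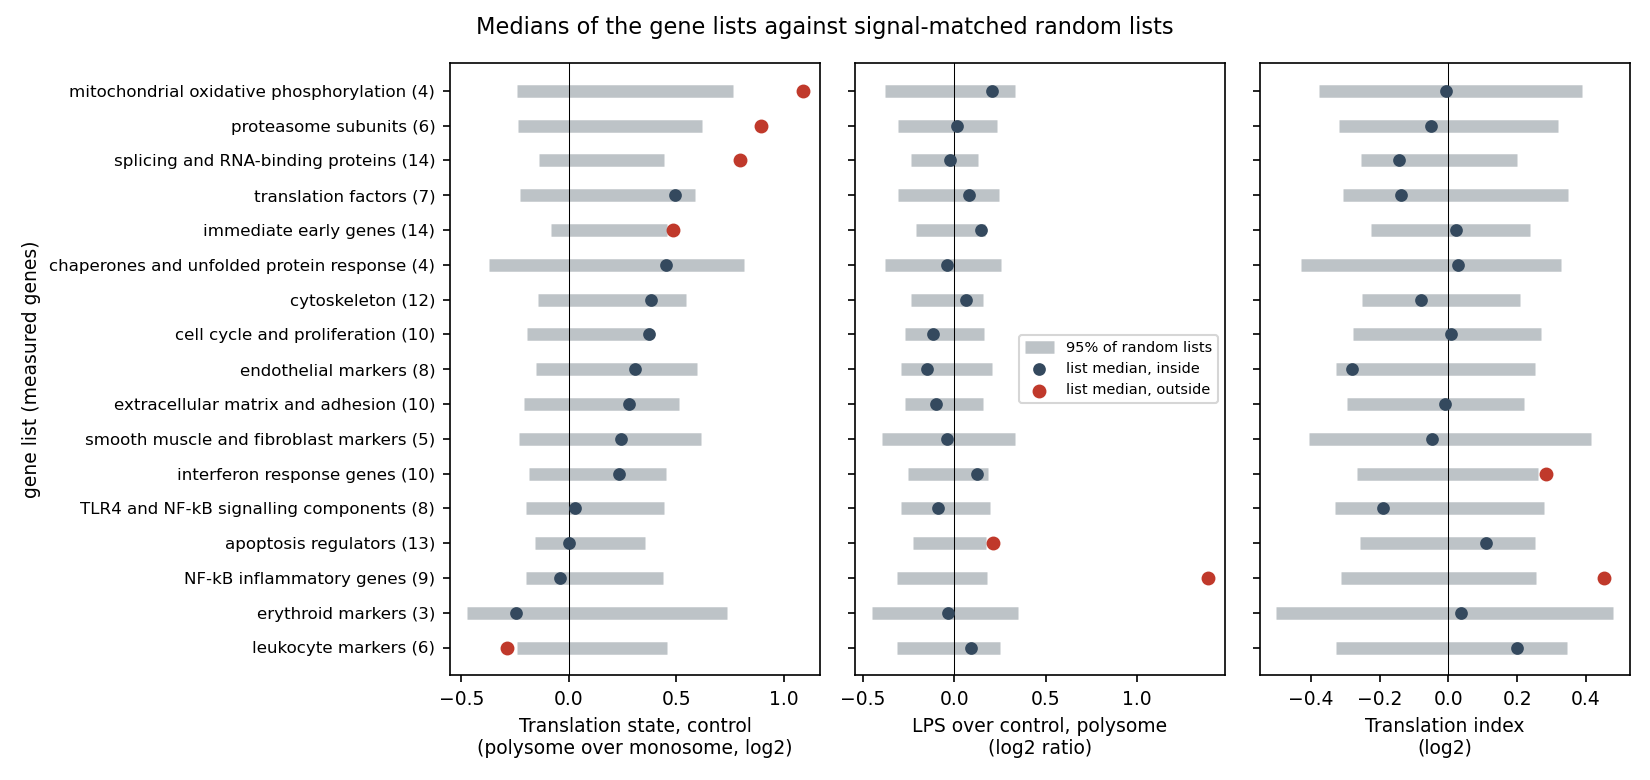
Median log2 of each gene list (points, number of measured genes in parentheses) for the control translation state, LPS over control in the polysome fraction and the translation index, with grey bars for the central 95% of 10000 random lists matched on signal. Red points lie outside the bar, and NF-kB inflammatory genes stand apart in the polysome panel at 2.62-fold and in the index panel at 1.37-fold.

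A control translation state of 2.5 or more was found for 98 spots and 0.4 or less for 7, and in LPS-treated cells for 103 and 9. High in both were 58 spots, where independent lists would share 3.26, and low in both were 3 against 0.0203. The brightest 41 spots had median translation states of 0.754 in control and 0.714 in LPS-treated cells, and the split of calls depended on the scaling. With scaling to the 75th percentile the split was 39 high against 20 low in control and 47 against 26 in LPS-treated cells, with quantile normalization 37 against 20 and 39 against 24, and with the loess trend removed 42 against 15 and 51 against 23. These settings moved the median log2 control translation state of all spots by -0.28, -0.18 and -0.15, and scaling to the filter median by -0.11, so a translation state is to be read against the median of all spots. Different spots of 1 gene resembled each other in translation state, with an intraclass correlation of 0.57 in control (one-sided permutation p = 0.00043, adjusted 0.00108) and 0.58 in LPS-treated cells (permutation p = 0.00022, adjusted 0.00108), over 25 genes, of which 21 have spots of the same clone accession.

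The last comparison asked for which mRNAs the distribution between monosomes and polysomes differed with LPS. RCAN1 had the highest translation index, 3.17, its translation state being 0.875 in control and 2.78 in LPS-treated cells. PLXNA3, a semaphorin receptor subunit, followed at 2.55, SOD2 at 2.18 and CFLAR, the last of the 12 highest, at 1.97. Between them lay CD163, CYTH1, BLZF1, SCNN1A, NELL1, RHOG, PPP1R10 and SMARCA2, from 2.15 to 2.00. The lowest was CCNT1, a subunit of the elongation factor P-TEFb, at 0.322, followed by the kinase MAP4K5 at 0.357, MOBP at 0.386, MPRIP at 0.395 and the ephrin receptor EPHB3 at 0.397. ZBTB14, NEK4, CADPS, DR1, SEMA3F, CDK6 and ELOC followed between 0.425 and 0.486. Several of these genes were dim, where background left in the signal weighs most. Over the 4 filters, signals ran from 0.189 to 0.328 of the filter mean for CD163, 0.190 to 0.382 for CYTH1 and 0.208 to 0.309 for NELL1. PLXNA3 ran from 0.197 to 0.353, CCNT1 from 0.186 to 0.700 and MOBP from 0.182 to 0.681. SOD2, CADPS and CDK6 were brighter, at 0.837 or more on every filter.

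The genes with high indices were of different kinds. RCAN1, SOD2 and CFLAR were higher with LPS in both fractions, and more so on polysomes. PLXNA3 stood at 1.48 on the polysome and 0.581 on the monosome filter, and PPP1R10 at 0.896 and 0.447. Among the low indices, CCNT1 was 3.57-fold higher on the LPS monosome filter with a polysome ratio of 1.15, while MAP4K5, MOBP and MPRIP had polysome ratios of 0.336, 0.326 and 0.396 beside monosome ratios of 0.939, 0.845 and 1.00. CDK6, a cell cycle kinase, had a translation state of 1.88 in control and 0.910 in LPS-treated cells.

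NF-kB inflammatory genes had a median translation index of 1.37 (9 genes, percentile 99.9), with 4 of 9 at 1.5 or more. TRAF1 had 2.34, SOD2 2.18, CD83 2.13 and IRF1 1.74, while CX3CL1 had 1.13. Control signals, monosome first, were 0.178 and 0.195 of the filter mean for TRAF1, 0.177 and 0.110 for CD83 and 0.151 and 0.198 for IRF1. CX3CL1 had 0.231 and 0.198, and SOD2 0.955 and 1.00. For TRAF1, CD83 and IRF1 the control monosome signal lay below the 25th percentile of its filter. The list lay inside the central 95% with signals floored at the 25th percentile of the filter (log2 median 0.23, percentile 96.0). It also lay inside over the genes above that percentile on every filter (0.15, percentile 87.9). These were only CX3CL1, GCH1, IER3 and SOD2, as TRAF1, CD83, IRF1, IL18R1 and IL15 dropped out. Interferon response genes had a median of 1.22 (10 genes, percentile 98.6), which lay inside the central 95% under 5 of 13 alternatives and, at percentiles down to 93.7, without 1 of 5 of its genes in turn. Immediate early genes had 1.01, endothelial markers 0.824 (percentile 5.09, inside), proteasome genes 0.965 and splicing and RNA-binding proteins 0.905. MMP14, a matrix metalloproteinase of the cell surface, had an index of 0.338 with a polysome ratio of 0.345, its LPS polysome signal of 0.121 lying below the 25th percentile of that filter.

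Past the limits of 2.5 and 0.4 were 5 spots with a high and 19 with a low translation index, of which 2 and 7 had a gene name. The split was 6 against 13 with quantile normalization, 22 against 34 with the 1st percentile subtracted as background and 2 against 6 with the pseudocount. The spread between spots of 1 gene was close to that over all spots: the SD of log2 was 0.37 between spots of 1 gene and 0.41 over all spots, and the intraclass correlation was -0.05 (one-sided permutation p = 0.593, adjusted 0.593), against 0.40 for the polysome LPS ratio (permutation p = 0.0128, adjusted 0.0213) and 0.21 for the monosome ratio (permutation p = 0.115, adjusted 0.144). All genes named by the size of their index have 1 spot each, so none of these values was measured a second time.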

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

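The translation index of EPHB3, a receptor for ephrins on the cell surface, was 0.397, with opposite ratios of at least 1.5-fold in the 2 fractions. Its LPS over control ratio was 0.649 on the polysome and 1.64 on the monosome filters. The difference between the fractions was not tested, since each ratio rests on 1 filter per treatment.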

How the results depend on the processing

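The filter that requires all 4 signals at or above the filter median was chosen after the data were seen, and the other settings before. No list median outside the central 95% changed sign. Genes named by the size of a ratio, picked for ratios far from 1, did not change sign in that ratio either. Other gene values given above, such as those of list members, were not part of this count. Scaling to the filter median moved the log2 monosome ratio of all spots by 0.047, past the -0.003 of IL15 and the -0.015 of DUSP5. The 75th percentile scaling moved the log2 control translation state by -0.28, past the 0.23 of SDHD. Directions of such values are not settled. Of the list medians inside the central 95%, 37 changed sign under at least 1 alternative, in 93 values, so their directions against a ratio of 1 are not settled. Part of these changes came from scalings that move all spots alike. The 75th percentile scaling, for example, took the median log2 control translation state of interferon response genes from 0.23 to -0.05. Such a shift leaves the place of a list among the random lists unchanged. Of 160 counts under alternatives, 98 stayed within 1.5 times the main count. Of 876 values of the genes named by size, 839 moved by less than 1 SD between spots of 1 gene. Of 1100 list medians, 1054 kept their side of the central 95%, 10 came to lie inside it and 36 outside it. These counts include scaling to the filter median, scaling to the 75th percentile and the values as deposited. Each of these shifts all spots alike, so apart from the random draw it could not move a list across the limits. Every count of list alternatives given here includes them, and a side kept under them is no sign of stability. No filter could be left out, and dim signals set the limit, since background values were not analysed here; the causes of the shifts were not tested, except that fewer items or wider limits alter counts by construction. Counts are high, then low.

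With the 1st percentile subtracted, control translation states gave 155 and 13 spots, LPS translation states 173 and 24, the index 22 and 34, low polysome ratios 32, low monosome ratios 18 and spots lower in both 13. With the pseudocount these were 65 and 2 for control, 67 high for LPS, 2 and 6 for the index, 5 low polysome ratios, monosome ratios 18 and 1, and 2 lower in both. The 75th percentile scaling gave 39 and 20 in control and 47 and 26 with LPS, loess 42 and 15 and 51 and 23, and quantile normalization 37 and 20 and 39 and 24. Scaling to the filter median and the values as deposited, which are identical, gave 14 low LPS translation states and 1 low monosome ratio. The index was high in 3 spots over spots bright on every filter, and in 3 over those with mean signal above the median. With all 4 signals at or above the filter median the index gave 2 and 9, and 16 spots were higher and 2 lower in both fractions. Per gene, control gave 21 and 4, LPS 15 and 3, the index 2 and 6, polysome ratios 14 and 9, monosome ratios 8 and 2, and both fractions 10 and 4. At limits of 2 and 0.5, control gave 219 and 25, LPS 232 and 31, the index 28 and 45, low polysome ratios 39 and low monosome ratios 18. At 1.5-fold, 68 spots were higher and 31 lower in both fractions.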

Other observations

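The tests of background in the induced spots, of the spots of 1 gene and of the size of the change in each fraction were chosen after the results were seen, and the tests of the loess trend and of the lower spots before. Several gene groups not described above had medians inside the central 95% of random lists in every ratio, though not under every alternative. Of 13 alternatives, 5 put the LPS translation state of cytoskeleton genes (percentile 97.2) outside, 2 the control translation state of cell cycle genes (percentile 97.1), and 1 each the LPS state of cell cycle genes and the control state of translation factors. Cell cycle genes (10 measured) had a control translation state of 1.30, and their LPS ratios were 0.923 on the polysome and 0.973 on the monosome filters. Cytoskeleton genes (12 measured) had 1.30, 1.04 and 1.02 in the same order, and ARPC2 was their only member above 1.5-fold on both LPS filters. Extracellular matrix genes (10 measured) had 1.21, 0.931 and 0.982, with the lowest polysome ratio in MMP14 at 0.345 and a mean log2 monosome ratio of 0.03, opposite in sign to the median. COL6A2, a collagen VI chain on the smooth muscle and fibroblast list, had polysome and monosome ratios of 0.447 and 0.840. Translation factors (7 measured) had 1.41, 1.06 and 0.960, with EIF1 and EIF4G1 each at 1.90 in control and a mean log2 polysome ratio of -0.02, opposite in sign to the median. Chaperones (4 measured) had 1.37, 0.973 and 0.942, with the chaperonin subunits CCT3 and CCT6A at 1.68 and 1.63.

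Some of the largest LPS ratios belong to spots that are unnamed here, 2 per direction being given. Spot 4000 was 17.7-fold higher on the polysome and 13.96-fold higher on the monosome filter, and spot 2543 was 11.7-fold and 12.9-fold higher. Spots 1324 and 1500 stood at 0.309 and 0.410 on the polysome filters and at 0.405 and 0.387 on the monosome filters. The same clone accession was listed for 2 spots in 33 cases, and the brighter of the pair exceeded the dimmer by a median of 2.73-fold, from 1.11-fold to 7.84-fold.

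Spots at least 2-fold higher with LPS in both fractions also leaned to polysomes, with a median translation index of 1.19 over 31 spots (bootstrap 95% interval over spots 1.05 to 1.60), 22 of 31 above 1, where all spots had 0.994. Against a trend with signal as the whole cause, the 31 spots had a median log2 index of 0.25 (0.01 to 0.62) with the loess trend removed. Over 16 spots with both control signals at or above the filter median it was 0.65 (0.11 to 0.88), or 0.66 (0.0021 to 0.90) with the 1st percentile subtracted. This split cannot exclude background, since background values were not analysed and these spots were not all bright. CFLAR, for example, had control signals of 0.308 and 0.305 of the filter mean. The other 15 spots had 0.17 (-0.14 to 0.46), and 0.066 (-0.18 to 0.56) over the 14 left after subtraction. Background stays open for both sets, and over all 30 spots left after subtraction the interval included 0, at 0.28 (-0.01 to 0.68). A steeper response of the LPS polysome filter would push spots at least 1.5-fold lower in both fractions the other way, and their median was 0.0014 (-0.18 to 0.05) over 31 spots, an interval that includes 0 and leaves this open, as it leaves differences between the cultures or gradients behind single filters. Ribosome loading of these mRNAs was not measured apart from these filters.

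A candidate explanation for most of the spread in the translation index is noise between spots, since each index combines 4 signals. Spots of 1 gene were no more alike in index than spots of different genes, with an intraclass correlation of -0.0451 over 25 genes (permutation p = 0.593), as noise would give. In 21 of these genes the spots share a clone accession, and of the 24 called spots 15 have no single gene name and 8 are the only spot of their gene in the set. The remaining one belongs to GRIA2, a glutamate receptor subunit named after its values were seen, with an index of 0.391 on that spot and 1.26 on its other spot in the set, of a different clone. Of the 24 spots past the limits, 12 had log2 ratios of at least 0.32 in size and of opposite direction in the fractions and 7 had the same direction in both, a division that does not tell a deviation on a single fraction from opposite movement in both.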
